A study of Medicago sativa with 9 samples.

How the data were processed

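Messenger RNA with poly(A) tails was sequenced on Illumina instruments from 9 alfalfa libraries, 3 each of wild type (WT), atp8-OE1 and atp8-OE2. The deposited table held whole-number read counts per annotated gene for each library, with the name and position of each gene. Reads had been aligned with HISAT2 version 2.2.1, and DESeq2 was also named, per the submitters' processing notes. The genome build, the annotation, the counting tool, its strand setting and its treatment of reads that match several places were not given in the sources used here. The authors' counts were used as deposited, with no rounding or rescaling before the tests.

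The table listed 127918 genes, of which 111950 carried an identifier beginning with Msa and 15968 an identifier given to loci found during assembly. In it, 118092 genes lay on 8 chromosomes that each appear in 4 copies, and 9826 lay on unplaced contigs. Alfalfa is a tetraploid, so most entries are allelic copies of a gene, and reads may be split between near-identical copies. Values of single copies are therefore uncertain. A further 3 lines held no identifier and no values and were left out, and 20750 gene ontology cells had been emptied and were not used. A Swiss-Prot protein name was given for 89476 copies, a name from the NR protein database alone for 32418, and no name for 6024. None of the identifiers (0) was found in the reference gene table at hand, so names and coordinates are those of the deposited table.

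Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter by group and the quasi-likelihood test on all 9 libraries, which shared their estimate of the spread. Benjamini-Hochberg adjusted p-values under 0.05 were called changed. After filtering, 72662 gene copies holding 98.96% of the counts were tested. Standard errors (SE) were taken as the fold change divided by the square root of the F statistic. CPM, the counts in 1e6 of a library, were computed from the deposited counts with TMM-scaled library totals. The test was run on simulated counts first, with 200 copies changed in each of 10 draws of atp8-OE1 against WT over 63262 to 63455 copies. It recovered 15.6% of changes of 1 on the log2 scale and 70.7% of changes of 2, with median fitted values of 0.99 and 2.01, and unchanged copies made up 6.09% of its calls. No call had the wrong direction (0), and 4.70% of unchanged copies had an unadjusted p under 0.05. In simulated data of both lines it recovered 36.7% of the shared changes with 2 false shared copies. In those of atp8-OE2 against WT, camera called the changed list in 10 of 10 draws and 0 of 330 unchanged lists. Far fewer copies changed in these simulations than were called in the data. The adjusted threshold was therefore stricter there, and the recovery rates do not carry over to the data.

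To describe genes rather than copies, counts were summed over copies with the same protein name, which gave 17262 tested sums, called summed genes here. Copies without a name were left out, and CPM of summed genes refer to the counts of named copies. All sums, their use in the description, and the rule for naming them were chosen after seeing the data. A shared name can also join paralogs, so a summed gene is a named protein, not a locus, and its change can rest largely on a single copy. Other sums used the best TrEMBL protein hit or the NR name.

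Fixed before the data were examined were the test, 34 gene lists defined by words in protein names, and the rule for named copies. The lists covered respiration and carbon metabolism, anther and pollen development, cell walls, hormones, stress and defence, growth, and markers of green tissue and other floral organs. Each was tested with camera from limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The fry test, which asks whether the genes of a set move on balance in a single direction without comparing them with other genes, was run as an alternative. Word matching took in other proteins, such as 4 summed genes with methylene in their names in the ethylene list. The pectin modification list took in inhibitors of pectin enzymes.

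Named copies had an adjusted p under 0.05, a mean of at least 2 CPM, group values that did not overlap and an informative protein name, with 1 copy per name. Non-overlap arises by chance in 10% of comparisons of 3 against 3. The 6 largest changes in each direction were taken for each line against WT, 8 in each direction for both lines together, 4 between the lines, and 3 members of each list. Named sums followed the same rule with at least 4 copies and 10 CPM. Other summed genes in the text, in the main results too, were examples chosen after their values were seen. They need not meet that rule: sugar transport protein 9 holds 1 copy and heat shock protein 90-1 holds 2. Where all libraries of a group were at 0, a bound on the fold was set against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval. Both cover counting error only. A median of a list was also computed with such members at their bounds.

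Total counts per library ranged from 9920930 to 13129089, so that 3 counts in a library corresponded to 0.229 to 0.302 CPM. Pairs of libraries within a group differed by more than sampling noise, with chi-square values per copy of 4.21 to 7.33, and none was treated as a duplicate. The extraction protocol describes biologically independent samples, but the sample titles give a single plant number to all libraries of an overexpression group, so that they may come from 1 plant or transformation event each. The p-values measure only the spread between these libraries, not between transformation events. Alternatives covered scaling by size factors or by library totals, other filters, the 2-group fits, limma-voom, DESeq2 1.42.0, a fold threshold, the replicate number as a block, and leaving out each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.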

Results

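The study title concerns atp8, a mitochondrial gene for a small subunit of the ATP synthase, and its part in cytoplasmic male sterility, a maternally inherited failure to make functional pollen. Messenger RNA was measured in WT alfalfa and in a pair of lines, atp8-OE1 and atp8-OE2, that overexpress atp8. Each group had 3 libraries. The sample labels give flowers as the tissue, and the extraction protocol speaks of anthers. Total counts were 10793022, 10051435 and 11176762 in WT, 11838656, 12435446 and 13129089 in atp8-OE1, and 10897613, 11931194 and 9920930 in atp8-OE2. Across genes, which are not independent replicates, Spearman correlations between libraries were 0.934 to 0.941 within groups. They were 0.770 to 0.776 between WT and atp8-OE1, 0.754 to 0.763 between WT and atp8-OE2, and 0.712 to 0.724 between the lines.

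None of the 127918 gene copies was named as atp8 (0), so the group labels could not be checked against the transgene. Of the copies, 25 carried names of proteins that plant organelle genomes encode, among them ATP synthase subunits alpha and 9. Most of these held few counts, and most lay on numbered chromosomes. Whether their reads came from an organelle was not tested. The copy with the most counts, of NADH-ubiquinone oxidoreductase chain 2 (Msa0997140), lay on such a chromosome too. Its counts were 73, 53 and 56 in WT. It had 249, 271 and 266 in atp8-OE1 and 196, 154 and 154 in atp8-OE2. The more abundant copy of ATP synthase subunit 9, on a contig, had 11, 11 and 19 counts in WT, 18, 26 and 19 in atp8-OE1 and 12, 13 and 14 in atp8-OE2, and was chosen here after its values were seen.

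The comparison of atp8-OE1 with WT asked which transcripts differed in the first overexpression line. Transcripts of a non-seed lectin, a carbohydrate-binding protein, rose from 1.15 ± 0.167 CPM (counts scaled to library size) in WT to 648 ± 114 CPM in atp8-OE1 (SD, n = 3). Most of this came from a single copy, at 0 CPM in WT and 481 CPM in atp8-OE1. Beta-glucosidase 25 rose from 6.18 ± 1.37 to 147 ± 4.99 CPM. Malate synthase, an enzyme of the glyoxylate cycle, fell from 75.8 ± 1.76 to 2.04 ± 0.491 CPM. A bark storage-like protein fell from 51.2 ± 0.296 CPM to 3 counts over the atp8-OE1 libraries, a ratio with a counting interval of 210 to 2980. Among summed genes, copies with the same protein name added up, 31 of 51 heat shock names were lower and 8 higher, and 18 of 27 histone names and 7 of 9 tapetum regulator names were higher. Camera called the heat shock and histone lists at its preset correlation but not with an estimated correlation (adjusted p = 0.403 and adjusted p = 0.478), and did not call the tapetum list (adjusted p = 0.335, Benjamini-Hochberg).

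Of 17262 summed genes, 4482 rose and 4984 fell in atp8-OE1. Among those named by the rule, the ribosomal RNA methyltransferase nep-1 rose from 26.2 ± 1.08 to 213 ± 7.80 CPM, and germin-like protein 8-14 from 6.36 ± 0.663 to 43.7 ± 4.24 CPM. Uroporphyrinogen decarboxylase, an enzyme of tetrapyrrole synthesis, rose from 2.69 ± 0.752 to 30.2 ± 19.1 CPM, with a wide spread between the atp8-OE1 libraries. DUF247 domain protein rose by 3.73 ± 0.14 (SE) on the log2 scale. Kunitz type trypsin inhibitor 104, a protease inhibitor, fell from 8.80 ± 0.734 CPM to 3 counts, with a counting interval of the ratio of 35.9 to 517. Hypersensitive-induced response protein 2 had a log2 fold change of -6.03 ± 0.39, a putative OB fold protein one of -5.71 ± 0.23, and a cytochrome cd1-nitrite reductase-like protein one of -5.30 ± 0.30. The largest adjusted p among the 12 summed genes named for this comparison was 7.21e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg).

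Single copies gave more and larger changes than summed genes: 19609 of 72662 rose and 23126 fell, and 32109 changed by at least 1 on the log2 scale. The copies that the rule named as higher had 0 counts in WT. They were a non-seed lectin copy (chromosome 6 copy 3, 45347376 to 45348605), at least 4790-fold higher with 17185 counts in atp8-OE1, sugar transport protein 13 (Msa0179770, chromosome 1 copy 4, 67471233 to 67472596), at least 1080-fold higher, and a retrovirus-related Pol polyprotein from transposon RE2 (chromosome 8 copy 4, 9078928 to 9083571), at least 684-fold higher. Copies of 60S ribosomal protein L31 (Msa0966750), a CCHC zinc finger protein (chromosome 4 copy 3, 50947951 to 50955891) and F-box/kelch-repeat protein At3g23880 (Msa1213030) were at least 648-fold, 534-fold and 297-fold higher. In the other direction, a copy of 40S ribosomal protein S4-2 (Msa0837200, chromosome 5 copy 4, 11021707 to 11024796) fell from 7186 counts in WT to 0, at least 2860-fold lower, while its protein name summed over all copies changed by -0.16 ± 0.05 on the log2 scale. Copies of serine hydroxymethyltransferase 4 (Msa0564110), isopentenyl-diphosphate delta-isomerase I (Msa1121830), a protein phosphatase 6 regulatory subunit (Msa0331940) and 60S acidic ribosomal protein P3-1 (Msa0566860) were at least 2300-fold, 1990-fold, 1470-fold and 1440-fold lower. A copy of polyubiquitin 11 (Msa0570630) had 11142 counts in WT and 1 in atp8-OE1, a ratio with a counting interval of 2390 to 526000.

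Among the 34 lists, that of heat shock proteins passed in atp8-OE1. Of its 344 copies, 171 fell and 76 rose (176 and 78 adjusted over the list alone), with a median log2 fold change of -0.65, or -0.63 with its 18 members at 0 in a group set to their bounds. Camera gave a Benjamini-Hochberg adjusted p = 0.00283, but adjusted p = 0.389 with an estimated correlation. Of 51 summed heat shock genes, 31 fell and 8 rose (33 and 8 adjusted over the list alone). The 18.2 kDa class I heat shock protein, a small chaperone, fell by 0.79 on the log2 scale and heat shock protein 83 by 2.05, whereas heat shock protein 90-1 rose by 0.37 ± 0.07 and the heat shock factor HSF30 by 0.79 ± 0.05. For summed genes the list had a camera, Benjamini-Hochberg adjusted p = 4.22e-06, and adjusted p = 0.403 with an estimated correlation.

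Histones, with 18 of 27 summed genes higher and 4 lower (18 and 4 adjusted over the list alone), and ribosomal proteins, with 91 of 212 higher and 35 lower (92 and 35 adjusted over the list alone), passed for summed genes in atp8-OE1, with camera, Benjamini-Hochberg adjusted p = 0.0172 and 0.0231. With an estimated correlation these were adjusted p = 0.478 and adjusted p = 0.782, and without WT replicate 1 ribosomal proteins lost the call (0.0531). For copies the lists did not pass, with camera adjusted p = 0.208 and 0.739, and there the mean log2 fold changes, -0.10 and -0.33, had the opposite sign of the medians, 0.35 and 0.12, and of the tests. Histone H4 variant TH011 rose by 0.67 on the log2 scale, from 2238 ± 195 to 3551 ± 228 CPM, probable histone H2A.2 from 192 ± 11.3 to 377 ± 35.2 CPM, and 60S ribosomal protein L3-1 by 1.06 ± 0.06 on the log2 scale. Of 9 tapetum regulators, which act in the cell layer that feeds developing pollen, 7 rose and 1 fell (7 and 1 adjusted over the list alone), among them ABORTED MICROSPORES from 106 to 136 CPM and MALE STERILITY 1 by 0.71 ± 0.16. The list did not pass, with a Benjamini-Hochberg adjusted p of 0.335 by camera. Of 18 pollen and anther proteins 1 rose and 9 fell (1 and 9 adjusted over the list alone), with a median of -1.15 and an adjusted p of 0.106 by the same test. Floral organ identity genes, markers of tissue outside the anther as well, had 8 of 44 higher and 19 lower (8 and 19 adjusted over the list alone), with a camera, Benjamini-Hochberg adjusted p = 0.722.

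The mitochondrial ATP synthase, the complex to which atp8 belongs, was not called by camera as a list in atp8-OE1. Of its 56 copies, 10 rose and 22 fell (10 and 22 adjusted over the list alone), with a median of -0.31 and a camera, Benjamini-Hochberg adjusted p = 0.591. The fry test, which asks whether members move on balance in a single direction without comparing them with other genes, called the list for copies (Benjamini-Hochberg adjusted p = 1.36e-05) and summed genes (0.00036), as it did 29 of the 34 lists of copies. Of its 14 summed genes, which include assembly factors and 2 subunits that plant mitochondria encode, 1 rose and 4 fell (0 and 3 adjusted over the list alone), with a median of -0.02. Subunit gamma fell by 0.52 and subunit d by 0.72 on the log2 scale. Subunit alpha fell by 2.67, but from only 226 counts over the WT libraries to 43, and to 48 in atp8-OE2. Much of that fall lay in a single copy on a numbered chromosome (Msa0929630). It had 48, 44 and 37 counts in WT, 0, 1 and 0 in atp8-OE1, and 1, 0 and 1 in atp8-OE2. In atp8-OE2, 4 rose and 2 fell (4 and 2 adjusted over the list alone), among them subunit delta', which rose by 0.79 ± 0.08, and subunit gamma, which rose by 0.47 ± 0.08, while subunit alpha fell by 2.51. Camera gave Benjamini-Hochberg adjusted p-values of 0.859 and 0.715 for the summed genes of the 2 lines, and in atp8-OE2 the mean, -0.13, had the opposite sign of the median, 0.01, and of the test. Complexes II to IV had 1 of 33 summed genes higher and 16 lower in atp8-OE1 (1 and 16 adjusted over the list alone), and 6 higher and 6 lower in atp8-OE2 (6 and 6 adjusted over the list alone), with camera, Benjamini-Hochberg adjusted p = 0.19 and 0.907. In atp8-OE2 the median, -0.08, and the mean, -0.04, of that list had the opposite sign of its test.

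In atp8-OE2, the question was the same for the second line, and among the 34 lists that of heat shock proteins had the smallest p. Their share of all counts was 6.69 ± 0.0612% in WT, 4.98 ± 0.178% in atp8-OE1 and 0.441 ± 0.0278% in atp8-OE2 (SD, n = 3). The 18.2 kDa class I heat shock protein fell from 21283 ± 1482 CPM in WT to 131 ± 5.06 CPM. Heat shock 70 kDa protein 4 fell from 9922 to 540 CPM, and heat shock protein 90-1 from 2692 ± 61.6 to 29.7 ± 3.59 CPM. The 17.1 kDa class II heat shock protein fell from 1556 to 1.73 CPM, a log2 fold change of -9.80 ± 0.09. The heat shock factor HSF30, a transcription factor of this response, fell from 391 ± 4.09 to 15.6 ± 0.939 CPM.

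**Figure D1:**
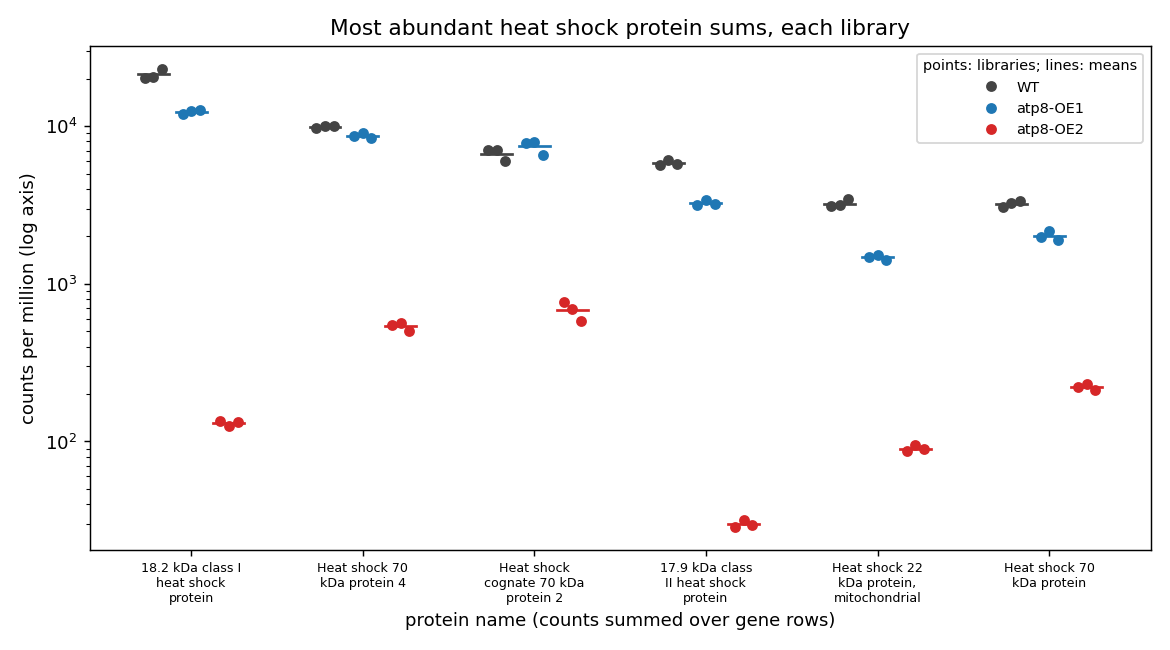
CPM on a log axis for the 6 heat shock protein names that were most abundant in WT, with a point for each library and a line at each group mean. For the 18.2 kDa class I heat shock protein the atp8-OE2 libraries averaged 131 CPM, against 21283 CPM in WT and 12349 CPM in atp8-OE1.

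Of the 344 heat shock copies, 234 fell and 55 rose in atp8-OE2 (235 and 56 adjusted over the list alone), with a median log2 fold change of -3.03, which did not move with its 33 members at 0 in a group set to their bounds. Camera gave a Benjamini-Hochberg adjusted p = 4.13e-69, and adjusted p = 0.000149 with an estimated correlation. Of the 51 summed genes, 36 fell and 5 rose (36 and 5 adjusted over the list alone), with a median of -3.33. The small heat shock protein of chloroplasts fell from 1720 ± 54.3 to 2.65 ± 0.470 CPM, heat shock protein 21 from 189 to 0.109 CPM, and the mitochondrial 26.5 kDa heat shock protein from 227 ± 10.8 to 0.640 ± 0.0699 CPM. The 18.1 kDa and 17.8 kDa class I proteins had log2 fold changes of -8.68 and -8.66. A copy of heat shock cognate 70 kDa protein (Msa0764230, chromosome 5 copy 2, 23891502 to 23893670) went the other way, from 0 counts in WT to 1751, at least 486-fold higher.

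The list named programmed cell death also passed for copies in atp8-OE2, with 43 of 112 lower and 26 higher (46 and 27 adjusted over the list alone) and a median of -0.47. Camera gave a Benjamini-Hochberg adjusted p = 0.0122, and adjusted p = 0.0762 with an estimated correlation. The members that fell most are chaperone regulators of the BAG family: BAG6 fell from 3125 ± 224 to 14.7 ± 1.96 CPM and BAG5 from 1102 ± 82.2 to 39.6 ± 1.51 CPM. BAG6 is also among the heat response genes examined further below, so this list is not independent of that set. Bax inhibitor 1, a suppressor of cell death, fell from 1177 ± 74.8 to 300 ± 26.1 CPM, while metacaspase-7, a cysteine protease, rose from 12.6 ± 1.85 to 46.8 ± 2.65 CPM. The call for programmed cell death was lost without any single library, with adjusted p-values of 0.145, 0.107 and 0.172 without WT replicates 1, 2 and 3, 0.105, 0.101 and 0.131 without those of atp8-OE1, and 0.105, 0.105 and 0.118 without those of atp8-OE2 (camera, Benjamini-Hochberg). Under scaling by library totals it was 0.0676. Of 23 summed genes of that list 8 rose and 10 fell (8 and 10 adjusted over the list alone), with camera, Benjamini-Hochberg adjusted p = 0.0333 and adjusted p = 0.298 with an estimated correlation.

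Over all names, 4882 of 17262 summed genes rose and 4714 fell in atp8-OE2. Peroxidase 25 rose from 2.25 ± 0.426 to 89.4 ± 2.08 CPM, subtilisin-like protease 3 from 3.38 ± 0.518 to 70.7 ± 15.4 CPM, and the non-specific lipid-transfer protein Cor a 8.0101 from 29.4 ± 3.03 to 288 ± 53.1 CPM. Ferredoxin-nitrite reductase, an enzyme of nitrogen assimilation, rose from 8.05 ± 0.582 to 64.4 ± 5.76 CPM. Mitochondrial uncoupling protein 5 fell from 2190 ± 71.7 to 687 ± 102 CPM, and copper-zinc superoxide dismutase from 397 ± 10.1 to 122 ± 11.3 CPM. Most of the superoxide dismutase change lay in a single copy (Msa1038680), at 260 CPM in WT and 0 in atp8-OE2. That of subtilisin-like protease 3 lay in Msa0754040, at 0 and 67.9 CPM. The pectin modification list holds enzymes that loosen or stiffen cell walls, and also inhibitors of such enzymes and non-catalytic subunits. Of its 76 summed genes, 43 were higher and 17 lower (43 and 17 adjusted over the list alone). Ethylene names had 22 of 97 higher and 41 lower (23 and 41 adjusted over the list alone). Both lists had a camera, Benjamini-Hochberg adjusted p = 0.0333. These were adjusted p = 0.247 and adjusted p = 0.476 with an estimated correlation, and pectin modification lost the call without WT replicate 1 (0.0621). For copies they were 0.0764 and 0.186. The ethylene-responsive factors ERF109 and ERF017 fell by 1.47 and 1.55 on the log2 scale.

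Among single copies, 19631 rose and 23245 fell in atp8-OE2, and 32676 changed by at least 1 on the log2 scale. Copies of 40S ribosomal protein S15a-1 (Msa1216530), subtilisin-like protease 3 (Msa0754040), 60S ribosomal protein L17-2 (Msa0421920) and F-box protein At1g80960 (Msa0253670) had 0 counts in WT and were at least 836-fold, 665-fold, 488-fold and 358-fold higher. A copy of 60S ribosomal protein L23 (Msa0075170) had 1 count in WT and 8335 in atp8-OE2, a ratio with a counting interval of 1240 to 274000. Copies of a cold and drought-regulated protein CORA (chromosome 5 copy 2, 67276009 to 67277748), superoxide dismutase (Msa1038680), the 17.1 kDa class II heat shock protein (chromosome 3 copy 1, 84216959 to 84217737), classical arabinogalactan protein 1 (Msa0560170) and the 18.1 kDa class I heat shock protein (chromosome 5 copy 4, 54910605 to 54911321) fell to 0, at least 3570-fold, 3110-fold, 2650-fold, 2640-fold and 2300-fold lower. A non-specific lipid-transfer protein copy (Msa1153970) had 20266 counts in WT and 1 in atp8-OE2, with a counting interval of 4370 to 962000. Scaling by library totals moved the median log2 fold change of all copies from -0.05 to 0.17, and with it 24148 copies rose and 20196 fell, the opposite balance. Relative to that median, the heat shock list stayed lower and past its threshold.

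Genes that changed in the same direction in both lines were examined because atp8 was overexpressed in each. Chitinase 2, an enzyme that degrades chitin, rose from 116 ± 40.2 CPM in WT to 720 ± 44.2 in atp8-OE1 and 635 ± 69.9 in atp8-OE2. The phosphatidylinositol transfer protein SFH6 rose from 14.1 ± 2.13 to 75.6 ± 3.61 and 74.2 ± 5.99 CPM. Malate synthase fell to 2.04 ± 0.491 and 2.11 ± 0.461 CPM, and Nudix hydrolase 23 fell by 3.47 and 3.52 on the log2 scale. The RNA-degrading enzyme 5'-3' exoribonuclease 3 fell from 903 ± 32.8 to 121 ± 6.56 and 75.5 ± 1.80 CPM.

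Of the summed genes, 2004 rose and 2355 fell in both lines, and 1805 changed in opposite directions. Metacaspase-7 rose by 2.01 ± 0.24 in atp8-OE1 and 1.90 ± 0.24 in atp8-OE2 on the log2 scale. V-type proton ATPase subunit d1 rose by 2.45 and 2.34, protein phosphatase 2C 16 by 2.21 ± 0.30 and 1.92 ± 0.30, and DEK domain-containing chromatin-associated protein 2 by 1.96 ± 0.17 and 1.68 ± 0.17. Peroxidases 9 and 40 rose by 1.32 and 1.58 in atp8-OE1 and by 1.62 and 1.53 in atp8-OE2. The transcription factor ATHB-40 fell from 67.0 ± 2.27 to 8.88 ± 2.21 and 8.53 ± 1.68 CPM. The pentatricopeptide repeat protein At1g53600, of a family that processes organelle RNA, fell from 46.9 ± 2.84 to 4.61 ± 0.168 and 5.76 ± 0.203 CPM, and an E3 ubiquitin ligase named MARCHF8 fell by 4.08 and 2.97 on the log2 scale. Among these named genes the largest adjusted p was 0.00033 (edgeR quasi-likelihood test, Benjamini-Hochberg).

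Single copies shared by both lines included several with no counts in a group. Copies of the homeobox protein ATHB-15 (Msa0224890), probable xyloglucan glycosyltransferase 5 (chromosome 7 copy 4, 26053781 to 26056380) and NO VEIN (Msa0998560) were at 0 in WT and at least 285-fold, 134-fold and 68.3-fold higher in atp8-OE1, and at least 183-fold, 71.6-fold and 150-fold higher in atp8-OE2. Copies of the zinc finger protein ZAT11 (Msa1078330), a purine-uracil permease (chromosome 6 copy 1, 3102579 to 3103928) and CONSTANS-LIKE 13 (Msa1081580) had 0 counts in both lines and were at least 779-fold, 612-fold and 456-fold lower in atp8-OE1.

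In all, 28795 copies changed in both lines, of which 7951 rose and 11120 fell in both and 9724 changed in opposite directions. Independent lists of the same sizes would share 5298 rising and 7398 falling copies. Of the copies changed in both lines, 66.2% changed in the same direction. Both comparisons used the same WT libraries, and 20 simulations of unchanged lines against them gave a highest count of 0 shared calls by edgeR, with at most 1 call in either line. Fold changes in the lines correlated across copies with r = 0.305 and a covariance of 1.87, against a mean r of 0.504 and covariance of 0.0811 in those simulations, a difference in covariance of 1.78. Of all tested copies, called or not, 58.6% had the same sign in both lines, against 66.9% in the simulations of no change. For summed genes r was 0.375 and the covariance 1.09, against 0.505 and 0.0324. With 3 WT libraries the controls could not be split into parts of at least 2. The simulations held only the spread between libraries, not differences between plants. Part or all of the excess may therefore come from the shared controls, and it does not measure a common effect of atp8.

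**Figure D2:**
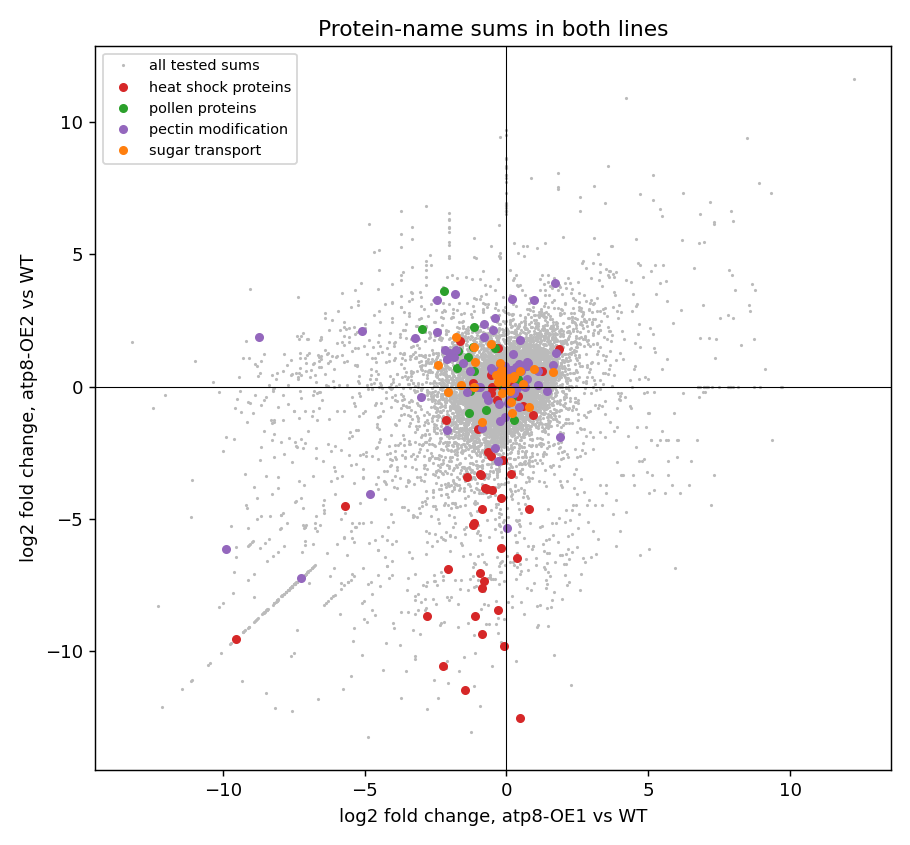
Log2 fold change of each of 17262 summed genes against WT in atp8-OE1 (horizontal) and atp8-OE2 (vertical), with heat shock, pollen, pectin and sugar transport names in colour; values of genes at 0 counts in a group depend on the prior count. The heat shock points lie far below 0 on the atp8-OE2 axis, with a median of -3.33, and closer to 0 on the atp8-OE1 axis, with a median of -0.56.

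The lines were compared directly to see where they differed from each other. For names of the pollen, pectin modification and sugar transport lists, more transcripts were higher than lower in atp8-OE2 against atp8-OE1. For heat shock proteins, more were lower than higher. Camera with an estimated correlation called the pollen, pectin and sugar transport lists for copies but not for summed genes. The anther-specific protein BCP1 was at 13.8 ± 1.23 CPM in WT, 6.22 ± 0.726 in atp8-OE1 and 65.7 ± 10.1 in atp8-OE2. Pectate lyase, which cleaves pectin, was at 237 ± 19.2, 65.2 ± 7.73 and 516 ± 47.7 CPM, and pectinesterase/pectinesterase inhibitor at 157 ± 6.51, 36.9 ± 1.08 and 322 ± 26.8 CPM. Sugar transport protein 9, a hexose carrier whose name covers 1 copy, was at 8.33 ± 1.59, 2.40 ± 0.395 and 30.6 ± 2.80 CPM.

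Of 72 pollen and anther copies, 37 were higher in atp8-OE2 than in atp8-OE1 and 15 lower (37 and 15 adjusted over the list alone), with a median log2 difference of 1.14. Of 18 summed genes 10 were higher and 3 lower (10 and 3 adjusted over the list alone), among them pollen-specific leucine-rich repeat extensin-like protein 3 by 3.04 ± 0.10 and pollen receptor-like kinase 1 by 2.49 ± 0.23. Sugar transport had 71 of 138 copies higher and 29 lower (72 and 30 adjusted over the list alone), with a median of 0.72, and 15 of 30 summed genes higher and 6 lower (16 and 7 adjusted over the list alone). Sugar transport proteins 10, 11 and 14 were higher by 2.63 ± 0.14, 3.25 ± 0.18 and 2.06 ± 0.09. Camera gave a Benjamini-Hochberg adjusted p = 0.0165 for each of the lists of pollen proteins and sugar transport, and adjusted p = 0.0499 for both with an estimated correlation. For summed genes these were camera, Benjamini-Hochberg adjusted p = 0.00204 and 0.0297, with adjusted p = 0.0864 and adjusted p = 0.148 with an estimated correlation.

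Pectin modification had 179 of 366 copies higher in atp8-OE2 and 104 lower (181 and 107 adjusted over the list alone), a median of 0.58, and camera, Benjamini-Hochberg adjusted p = 0.0484, with adjusted p = 0.0499 with an estimated correlation. Of 76 summed genes 40 were higher and 19 lower (43 and 19 adjusted over the list alone), with adjusted p = 0.00204 and, with an estimated correlation, adjusted p = 0.0521 by the same test. Probable pectate lyase 22 was higher by 2.61 ± 0.23, and probable polygalacturonase At3g15720 had a log2 difference of -2.49 ± 0.10. The copy-level call for pectin modification was lost without WT replicates 1, 2 and 3 (camera, Benjamini-Hochberg adjusted p = 0.075, 0.0821 and 0.0874), without atp8-OE1 replicates 1 and 2 (0.0737 and 0.0717) and without atp8-OE2 replicates 1, 2 and 3 (0.0599, 0.0837 and 0.0672). It stayed at 0.0475 without atp8-OE1 replicate 3.

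Beside these groups, markers of green tissue and of floral organs, stamens among them, were measured. Photosynthesis names had 11 of 43 summed genes higher in atp8-OE2 than in atp8-OE1 and 15 lower (11 and 15 adjusted over the list alone), with a median of -0.09, and floral organ identity names 20 of 44 higher and 9 lower (20 and 9 adjusted over the list alone), with a median of 0.26. Neither list passed, with camera, Benjamini-Hochberg adjusted p = 0.657 and 0.4. The petal and stamen regulator TM6, at 429 CPM in atp8-OE2 and 214 in atp8-OE1, was higher by 1.01 ± 0.08.

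Heat shock proteins were lower in atp8-OE2 than in atp8-OE1 in 225 of 344 copies and higher in 61 (229 and 62 adjusted over the list alone), with a median of -1.94, or -1.91 with 45 members at 0 in a group set to their bounds. Camera gave a Benjamini-Hochberg adjusted p = 9.78e-23, and adjusted p = 0.00472 with an estimated correlation. Of 51 summed genes 34 were lower and 6 higher (34 and 6 adjusted over the list alone), and HSF30 had a log2 difference of -5.44 ± 0.06. Lipid transfer proteins and oleosins passed for summed genes, with 23 of 40 higher and 9 lower (23 and 10 adjusted over the list alone), as did ethylene names, with 20 of 97 higher and 41 lower (20 and 41 adjusted over the list alone), and programmed cell death, with 4 of 23 higher and 11 lower (4 and 11 adjusted over the list alone). Their camera, Benjamini-Hochberg adjusted p-values were 0.00204, 0.03 and 0.00204, and with an estimated correlation adjusted p = 0.636, adjusted p = 0.636 and adjusted p = 0.148. Ethylene lost the call without atp8-OE1 replicate 3 (0.0518). For copies the values were 0.0888, 0.407 and 0.055. The lipid-transfer protein Cor a 8.0101 was higher by 5.73 ± 0.16, and the differences of BAG6 and ERF017 were -6.94 ± 0.11 and -1.62 ± 0.05.

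Between the lines, 5188 of 17262 summed genes were higher in atp8-OE2 and 5078 lower, and of single copies 22401 and 23591. Bark storage-like protein reached 107 ± 7.33 CPM in atp8-OE2 against 3 counts in atp8-OE1, a ratio with a counting interval of 439 to 6230. DNA replication factor CDT1-like protein was at 42.1 ± 1.79 CPM against 0.873 ± 0.394 CPM. The non-seed lectin was at 1.89 ± 0.646 CPM in atp8-OE2 against 648 ± 114 in atp8-OE1. Copies of elongation factor 1-alpha (Msa1315690) and isopentenyl-diphosphate delta-isomerase I (Msa1121830) were at least 1300-fold and 1790-fold higher in atp8-OE2, and a copy of cytochrome c (Msa1121390) at least 2140-fold lower. Scaling by library totals moved the median difference of all copies from -0.02 to 0.15, and with it 25619 copies were higher and 20726 lower, the opposite balance.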

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

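The tests of atp8 as the main cause, of alleles behind the heat shock and pollen patterns, of a heat response, of anther stage and of other floral organs, and all sums over copies, were chosen only after the result was seen.

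The direct test between the lines picked out 45992 gene copies that differed, and 9724 that had changed in opposite directions against WT. Lists that differed between the lines by camera were those of pollen proteins, with a median log2 difference of 1.14 in atp8-OE2 over atp8-OE1, sugar transport, with 0.72, pectin modification, with 0.58, and heat shock proteins, with -1.94. With an estimated correlation these calls held for copies, at adjusted p = 0.0499 for each of the first 3 and adjusted p = 0.00472 for heat shock proteins. For summed genes those of pollen proteins, sugar transport and pectin modification were lost (adjusted p = 0.0864, adjusted p = 0.148 and adjusted p = 0.0521). With the replicate number as a block, the copy calls of pollen proteins and pectin modification were lost too. Among named summed genes, those that moved in opposite directions against WT and differed between the lines in a direct test were beta-glucosidase 25, by -6.85 on the log2 scale, the lipid-transfer protein Cor a 8.0101, by 5.73, DNA replication factor CDT1-like protein, by 5.59, and subtilisin-like protease 3, by 5.20. For bark storage-like protein and Kunitz type trypsin inhibitor 104, with 3 counts each in atp8-OE1, the ratio between the lines was no lower than 439 and 133 by its counting interval. Among single copies the difference was at least 5600-fold for 40S ribosomal protein S4-2 (Msa0837200), 2620-fold for 60S acidic ribosomal protein P3-1 (Msa0703370) and 1300-fold for elongation factor 1-alpha (Msa1315690), all higher in atp8-OE2. It was at least 3260-fold for a copy of mitochondrial prohibitin-3, which was lower in atp8-OE2.

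Most copies that passed the filter differed between each pair of groups. Library size or scaling was argued against, since the count in atp8-OE1 against WT changed by a ratio of at most 1.00 under other scalings (1.00108). Library totals moved the count of atp8-OE2 against WT from 42876 to 44344, and that between the lines from 45992 to 46345. In both they turned the balance of higher and lower copies. Overexpression of atp8 as the main cause could not be judged from these counts. The lines differed from each other in 45992 copies, and in no fewer than 44349 with a library left out. That was more than either differed from WT (at most 41962 with a library left out), which met the bound written against this cause. The counts were known when that bound was written. An equal effect in both lines would not make them differ, but effects particular to a line would, and no copy was named as the transgene. Neighbouring copies of different proteins on a chromosome copy moved together more than the summed genes of the same names, by 0.148 in correlation at the least (0.203 against 0.0552 over 59107 pairs). This met the bound set in advance for blocks of differing alleles in the plants compared. The sums add copies from other places in the genome, so their neighbours correlate less whatever acts locally. The excess therefore cannot tell differing alleles from other local causes. A test of single genes stayed undecided. It had 1170 cases of a copy silent in a group, where a copy can count in more than 1 comparison. Of these, 27.5% belonged to a protein whose sum stayed within a log2 change of 1, between the bounds set in advance. Only 850 cases lay in a sum of 2 or more copies and could meet that criterion. Differing plant genotypes may be a candidate explanation but cannot be told apart from other causes for these copies.

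The heat shock list was far lower in atp8-OE2. Allelic differences that cancel between the copies of a name were argued against. Sums over all copies of each name had a median log2 fold change of -3.33 (bootstrap interval -4.63 to -1.27, which treats co-expressed genes as independent). Sums by best protein hit had a smaller median of -1.27, with 76 of 120 lower and 21 higher. Neither kind of sum can test a genotype that acts on many of these genes together. A heat response that differed between the plants at harvest could account for it. Among 12 summed heat response genes outside the heat shock names, 9 fell and 2 rose, with a median of -3.01. BAG6 of the programmed cell death list, whose fall is given above, is among these 12. The interval of -5.79 to -0.01 left a heat response open, although the median itself met the bound written for the test. Time of day was undecided too, with morning clock genes above evening clock genes by 0.62 (interval 0.14 to 1.79). The sources used here give no day, time or conditions of harvest, and the transgene and any genotype of a line go with the group, which keeps these explanations, and an effect of atp8 itself, open.

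More pollen, pectin and sugar transport names were higher than lower in atp8-OE2 against atp8-OE1, although camera with an estimated correlation called none of these lists for summed genes. Allelic differences that cancel between the copies of a name were argued against by the sums over copies. Their pooled median was 0.46 with 65 of 124 higher and 28 lower, but they cannot test a genotype that acts on many genes together. A loss of other floral organs in atp8-OE2 needed a clear fall. Medians of -0.088 for photosynthesis and 0.26 for floral organ names did not show it. Such a loss was not excluded, as the floral organ list also holds stamen regulators such as TM6, and a gain of organs was not tested. Of 31 summed genes of earlier anther stages (tapetum, exine and meiosis), 13 were called lower and 3 higher, with a pooled median of -0.23 and 24 below 0 (exact sign test p = 0.00333, which treats co-expressed genes as independent), but camera called none of the 3 lists (Benjamini-Hochberg adjusted p = 0.53, 0.412 and 0.648). Anthers at a later stage in atp8-OE2 than in atp8-OE1 may therefore be no more than a hypothesis, found and tested on the same data. Whether atp8 or the harvest set such a difference was not tested.

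Splits of the 6 libraries of each comparison into other groups of 3 number 10 with the real split, which itself was the 1 split with as many calls, too few for a share under 0.05. In fits of those 6 libraries the real splits gave 41099, 40095 and 43494 changed copies by edgeR for atp8-OE1 against WT, atp8-OE2 against WT and between the lines. The highest of the other splits gave 0 in each, with 444 to 640, 431 to 615 and 347 to 537 copies at an unadjusted p under 0.05. Every other split mixed libraries of both groups, so the group difference entered the spread and kept calls low. These splits therefore do not measure what chance alone would give.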

How the results depend on the processing

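Sums over copies, including those by best protein hit and NR name, were alternatives chosen after seeing the data. The counts of changed copies stayed close to their values under other scalings, filters, tools and fits, and with a library left out, where they were 40227 to 40882 for atp8-OE1, 40396 to 41962 for atp8-OE2, 44349 to 45050 between the lines and 17370 to 19525 for both lines in the same direction. A fold threshold of 1 on the log2 scale left 12681 copies changed in both lines, by its construction. Sums test fewer units, and gave 17582, 18038, 19011 and 8088 (best hit), 9466, 9596, 10266 and 4359 (protein name) and 13950, 14237, 15029 and 6504 (NR name) for the same results. The correlation of the lines, 0.305, was 0.354, 0.375 and 0.371 with these sums and 0.307 to 0.323 with a library left out, and the cause was not tested. Of 34 lists, 1, 2 and 4 passed camera in the 3 comparisons. With an estimated correlation 0 passed in atp8-OE1 and 1 in atp8-OE2, and fry, which asks another question, called 29, 26 and 25. Best-hit sums gave 2 lists in atp8-OE1, and protein-name sums 3, 4 and 7. With a library left out 1 list passed in atp8-OE1 and 1 in atp8-OE2, and 3 to 6 between the lines. The replicate numbers paired the libraries weakly if at all. Same-numbered libraries had correlations of their deviations of 0.00455 to 0.0539, all above 0, and others -0.0572 to 0.0344, mostly below it. A pairing was therefore not excluded. With the replicate number as a block, 41974, 42045, 45398 and 18638 copies were called, r was 0.305, and 0 lists passed in atp8-OE1 (heat shock proteins 0.057) and 2 between the lines (pollen proteins 0.058 and pectin modification 0.0754 did not). In atp8-OE2 programmed cell death (0.27) lost and pectin modification (0.0398) gained the call. For sums between the lines the block left only heat shock proteins of the 7 lists, with pollen proteins and sugar transport at 0.0602 and pectin modification at 0.0511. The cause of the changes in lists was not tested. For 141 named copies, 3784 of 3807 values under the alternatives kept direction and call, 20 lost the call, 3 gained it, and 0 turned. DESeq2 gave no adjusted p for 289 copies. In simulated data of atp8-OE1 against WT, changes of 1 on the log2 scale were recovered in 0.556% of copies with 20 to 50 expected counts a library, 9.66% with 50 to 200 and 50.4% above, where the spread was lower too (median coefficients of variation 0.220, 0.181 and 0.132), so that depth and spread were not separated. Few copies changed in those simulations, so their adjusted threshold was stricter than that of the data, and the rates do not give the sensitivity reached here.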

Other observations

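The sums in these paragraphs, and the genes named in them, were chosen after seeing the data, while the lists were fixed before. Alternative respiration, the oxidases and uncoupling proteins that bypass ATP synthesis, had 8 of 17 summed genes lower and 3 higher in atp8-OE2 (8 and 3 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0696), and 9 lower and 1 higher in atp8-OE1 (9 and 1 adjusted over the list alone; 0.109). Ubiquinol oxidase 1 fell by 1.30 on the log2 scale in atp8-OE2 and by 0.38 in atp8-OE1, and the log2 fold changes of uncoupling protein 3 were -1.68 and -1.84. Scavengers of reactive oxygen had 13 of 33 lower and 5 higher in atp8-OE2 (13 and 5 adjusted over the list alone; adjusted p = 0.181 by the same test), among them cytosolic ascorbate peroxidase, which fell by 0.60, and the copper chaperone for superoxide dismutase, which fell by 1.68. Pentatricopeptide repeat proteins, which process organelle transcripts, had 112 of 316 higher and 43 lower in atp8-OE2 (110 and 43 adjusted over the list alone), and 102 higher and 59 lower in atp8-OE1 (97 and 58 adjusted over the list alone), with adjusted p of 0.142 and 0.335 by camera with Benjamini-Hochberg adjustment.

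Among hormone and defence names, the gibberellin-regulated protein 4 rose from 487 CPM in WT to 974 CPM in atp8-OE2 and fell to 316 CPM in atp8-OE1, and protein GAST1 was at 145, 258 and 58.9 CPM in the same order. WRKY transcription factors 33, 53 and 70 fell by 1.22, 1.19 and 1.96 on the log2 scale in atp8-OE2, whereas WRKY 33 rose by 1.17 in atp8-OE1. Phenylalanine ammonia-lyase, which opens the phenylpropanoid pathway, rose by 0.92 in atp8-OE1 and 1.10 in atp8-OE2. The exine enzyme type III polyketide synthase B rose from 64.9 ± 4.48 CPM to 203 ± 6.21 in atp8-OE1 and 130 ± 6.49 in atp8-OE2. Beta-amylase 1, which degrades starch, fell by 1.64 in atp8-OE2. These single genes were chosen after their values were seen.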
